A study of Drosophila melanogaster with 7 samples.

How the data were processed

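Genomic DNA from embryos of 7 Drosophila melanogaster translocation strains was compared by array comparative genomic hybridisation with DNA from embryos of the laboratory strain Oregon R. Per the labels, each translocation breaks in the heterochromatin of the right arm of chromosome 2 (2R), males of each strain were crossed to females carrying the compound chromosome C(2)EN, and embryos lacking 2R were picked because they did not form a ventral furrow at gastrulation. Strain embryos were 3.5 to 8 h old and reference embryos 0 to 8 h old. Strain DNA was labelled with Cy5 and Oregon R DNA with Cy3 on all 7 arrays, so a log2 ratio of Cy5 over Cy3 is the strain over the reference, and no dyes were swapped. There was 1 array per strain. The labels do not say whether DNA came from separate collections, so p-values over arrays measure only the spread between these strains.

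Per the file headers, the authors' arrays were read with Agilent Feature Extraction 9.5.3.1 under a CGH protocol, and the deposited processed intensity of each channel is background-subtracted, detrended and linearly dye-normalized. Probe positions are in the dm3 build (BDGP Release 5), per the file headers. Each array held 103747 spots besides 1325 control spots, which gave 83472 probes after averaging spots of 1 probe (79604 probes had 1 spot, 2045 had 2 and 1823 had 11). The submitters' processing notes name limma without a version. The authors' deposited value table holds log ratios, read here as log2, with 1 value per probe. Set against the scanner values of the same array, its columns had the same sign (Pearson r 0.911 to 0.948 across probes, which are not independent replicates) and a slope of 0.481 to 0.665. Its column medians were -0.193 for ftz[Rpl], -0.043 for B[SV5], 0.054 for B63, -0.034 for B238, -0.091 for bxd[68], -0.127 for G10 and -0.015 for E(da). Its direction follows from that comparison, while its log base, narrower scale and centring stay unknown. That table was used only as an alternative. It held 0 columns from outside the 7 arrays.

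Log2 ratios were computed from the processed signals and centred on each array's median, with no loess or quantile step. Control spots and spots marked as outliers by the scanner software (0.8% to 1.58% per array) were left out, and no spot was saturated. Probes had to be well above background in the reference channel on all 7 arrays, which left 78099 probes of 81464. The percentage of spots well above background was 97.6% to 98.9% in Cy3 and 94.9% to 98.6% in Cy5. Of the probes kept, 22949 had a position in the build. Most of these lay on a chromosome arm or its heterochromatin scaffold, but 198 lay on U and 156 on Uextra, which belong to no arm, and 29 on the mitochondrial genome. The rest came from other unplaced sequence. The precision of each value is limited by having 1 array per strain.

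A copy index placed each probe between the 2 levels known on each array. It was 0 at the array's median over the distal part of 2R (2168 probes beyond position 11346677) and 1 at its median over 2L, and it does not depend on centring. A probe was called lost below 0.33, kept above 0.67 and intermediate otherwise. Windows of 10 kb with at least 5 probes had been chosen for 2R heterochromatin, and unplaced scaffolds with at least 5 probes, but none had that many, so single probes were called instead. The error of the calls was read from 2L and from distal 2R. The 2R breakpoint was fitted on each array as a single change between the 2L level and the distal 2R level, with the least sum of absolute deviations, along 288 probes of the 2R heterochromatin scaffold (2RHet) and the adjoining 2.0 Mb of 2R. Intervals were 95% intervals from 1000 bootstrap draws of probes, and they cover scatter between probes of 1 array only. Nested order was scored as the number of probes whose calls fit 1 order of the strains, against 1000 relabellings of the strains within probes. On 3L and 3R, medians of 100 kb windows were searched for at most 1 step per arm. A step was called if its levels differed by over 0.2 (log2) and it improved the fit more than in each of 100 shuffles of window order.

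Differences between arm medians were tested by exact two-sided sign-flip permutation over the 7 arrays with Benjamini-Hochberg adjustment over 6 differences, and differences between the classes by exact two-sided permutation over the 35 splits of 7 arrays into 4 and 3. Probes were compared between the classes with limma (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Scan information in the files gave 4 slides and 3 scan days, which fell into 2 scan periods. Period 1 held B63, B238, bxd[68] and E(da), and period 2 held ftz[Rpl], B[SV5] and G10, so each period held both classes. In period 1, bxd[68] and E(da) were on slide 1 and B63 and B238 on slide 2, scanned on separate days, so class cannot be told apart from slide and day there. In period 2, ftz[Rpl] and B[SV5] were on slide 3 and G10 was the only array on slide 4, and the second-third class had 1 array.

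Genes were named from the accessions and names in the scanner files through a table of Release 6 genes, used for names and chromosomes only and never for coordinates. Of 78099 probes, 17053 were named by accession, 1870 by symbol and 1153 by synonym, and 58023 stayed unnamed. Of the 22949 probes with a position in the build, 20072 were named. A gene's value is the median over its probes. The rule for named genes was fixed before the data were examined. It took every gene of 10 lists of chromosome markers with at least 3 probes, the nearest gene with at least 3 probes on each side of a break, the 10 genes with the largest range of index over strains among genes with at least 5 probes, and, for the class contrast, the 20 genes with most passing probes. Of 77 genes on the lists, 24 had at least 3 probes, 41 had 1 or 2 and 12 had none. The spans of Release 5 genes were not used here, so probes annotated to a gene stood for it. Other genes named in the text were chosen after their values were seen, and the text says so.

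The methods were tested on simulated data, of which only the breakpoint runs drew values from these arrays. Simulated breakpoints among 120 probes, with the scatter of 2L probes, were placed exactly in 84.0% of runs for ftz[Rpl] and in 93.0% to 100.0% for the other strains, at most 5 probes off. These runs held no probes that stay high in all strains, so their accuracy does not describe the fits to the 288 or 235 real probes. Simulated steps were called in 50 of 50 arms with a step and 0 of 50 without. Those arms held independent normal noise and were set against fewer shuffles than the real search, so these rates do not describe it on real windows. In a simulated class contrast on 78099 probes, 2 of 50 probes changed by 1 (log2) were called, 25 of 50 changed by 2, 80 of 100 changed by 4, and 9 unchanged probes. Its noise took the spread of each real probe but was independent between probes and arrays. It therefore held no structure by scan period, and its error rate does not describe the real contrast.

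Alternatives fixed before the data were examined were normexp background correction (offset 50) on the mean and background signals, loess within each array, no filter on dim probes, the deposited table, centring on 3L, leaving out each strain, slide as a fixed or random block, 2 free levels for the breakpoint, other thresholds for the index and windows of 250 kb on the third chromosome. Alternatives chosen after seeing the data were the breakpoint without the 2RHet probes whose index was above the midpoint in all 7 strains, scan period as a fixed block and the class contrast within each period. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.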

Results

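Copy number along the genome was measured in embryos lacking most of the right arm of chromosome 2, from 7 translocation strains that share a break in 2R heterochromatin but differ in where it lies. In 4 strains the partner is the Y chromosome, T(Y;2)B[SV5], T(Y;2)B63, T(Y;2)B238 and T(Y;2)G10, called Y-autosome strains here. In the other 3 it is the third chromosome, T(2;3)ftz[Rpl], T(2;3)bxd[68] and T(2;3)E(da), called second-third strains. Each strain was hybridised once against Oregon R embryo DNA on an array rich in heterochromatin probes, and all values are log2 ratios of strain over reference. The design asks how far into 2R heterochromatin sequence is lost in each strain, and which unplaced sequence goes with it. With 1 array per strain there are no replicates of a strain, and errors over strains hold the differences between their translocations.

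Embryos of all 7 strains had much lower 2R signal than 2L signal, and 2L was itself below 3L. The median 2R probe lay 3.30 ± 0.77 (SD, n = 7) below the median 2L probe on the log2 scale, as a 2R minus 2L difference of -3.30, and was below it in 7 of 7 strains. The size of this difference depended on the processing: it was -2.20 with normexp, -1.99 with loess and -1.57 in the deposited table, each also below 0 in 7 of 7 strains. 2L minus 3L was -1.0 ± 0.20 (SD, n = 7), lower in 7 of 7 strains, where 1 copy against 2 gives -1.0. The mean of 2L minus 3L was -0.93 without G10, -0.91 with normexp, -0.82 with loess and -0.81 in the deposited table. The small chromosome 4 was also below 3L in 7 of 7 strains, by a mean of -0.19 ± 0.23 (SD, n = 7), but that mean was -0.11 without G10. All 3 differences had p = 0.0156 in the exact two-sided sign-flip permutation test, the smallest p that 7 arrays can give, and an adjusted p of 0.0312. The other 3 did not pass: 3R minus 3L was 0.03 ± 0.31, X minus 3L 0.09 ± 0.30 and Y minus 3L 0.02 ± 0.77 (SD, n = 7, exact adjusted p = 0.953, 0.727 and 0.953), and with loess within arrays Y minus 3L became 0.64 with an exact adjusted p = 0.0469. The Y level on each array was the median of only 17 probes. By scan period, the mean of 2R minus 2L was -3.69 over the 4 arrays of period 1 and -2.80 over the 3 of period 2, and that of 2L minus 3L was -0.93 and -1.10.

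**Figure D1:**
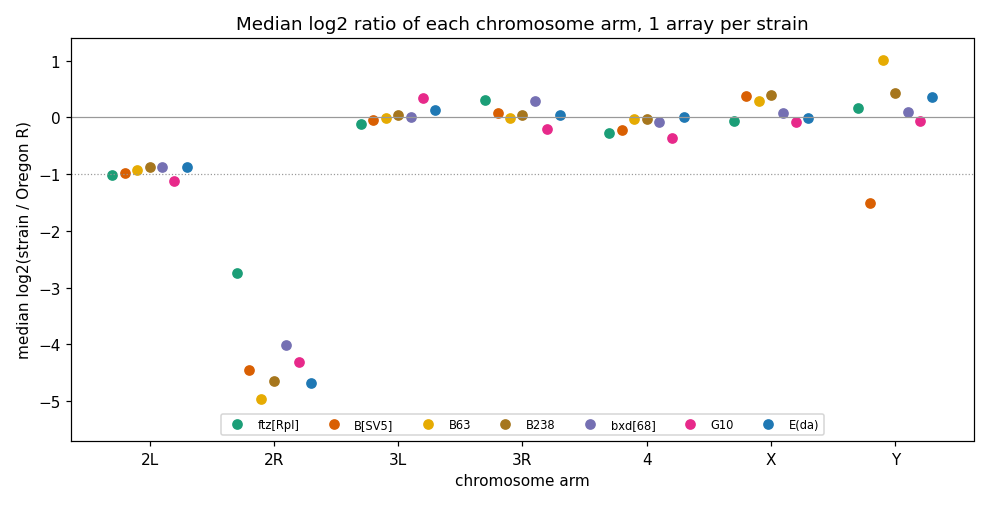
Median log2 ratio of strain over Oregon R (vertical axis) for each chromosome arm (horizontal axis), with 1 point per strain and a dotted line at -1. All 7 strains lie near -1 on 2L, between -4.96 and -2.73 on 2R, and spread from -1.51 to 1.01 on the Y.

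The 2R signal that remained differed between strains, and both its level and its order changed with the processing. 2R signal was 6.1% of 2L signal in B63, 7.1% in E(da), 7.3% in B238, 9.0% in B[SV5], 10.9% in G10, 11.5% in bxd[68] and 30.3% in ftz[Rpl]. These percentages ran from 14.8% to 41.4% with normexp, 12.4% to 39.0% with loess and 29.3% to 40.9% in the deposited table. ftz[Rpl] was highest except under loess, where G10 was at 39.0% and ftz[Rpl] at 38.9%, and B63 was lowest in each. Listed genes of the euchromatic arm with at least 3 probes were at the level of the distal arm: EcR, the ecdysone receptor, ap, a homeodomain selector gene of the wing, and bw, an eye pigment transporter gene, had copy indexes from -0.42 to 0.03 in all 7 strains, against 0 for distal 2R and 1 for 2L. They were the only 3 of the 9 listed euchromatic 2R genes with that many. Of those with fewer, inv, eve and shg (1 probe each, chosen after their values were seen) lay higher, at 0.71 to 0.79, 0.47 to 1.35 and 0.16 to 0.52. Between 0.1% (ftz[Rpl]) and 15.5% (B238) of 2R probes were not well above background in the strain channel, so the remaining signal is an upper estimate there. A class difference in 2R minus 2L was not detected (-3.62 ± 0.36, n = 4 Y-autosome, against -2.89 ± 1.07, n = 3 second-third; exact permutation p = 0.229, adjusted p = 0.643 over 10 class differences), but the smallest p of 35 splits is 0.0286, which for 1 difference alone would adjust to 0.286. It was -0.43 within scan period 1, where the classes lay on separate slides, and -1.61 within period 2, where ftz[Rpl] was the only second-third array.

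Among 2R heterochromatin genes with at least 3 probes, rl, l(2)41Ab and MFS17 separated the strains into 3 sets by where sequence stopped being kept. MFS17 was on no list and came in only through the breakpoint fit that was chosen after seeing the data. rl, which encodes the MAP kinase ERK, and l(2)41Ab were at 2L dose in ftz[Rpl], B[SV5], B63 and B238 (indexes 0.94 to 1.0 and 0.89 to 0.99) and low in bxd[68], G10 and E(da) (0.23, -0.26 and -0.06 for rl, and 0.00, -0.10 and 0.01 for l(2)41Ab). MFS17, further along the scaffold at 1265541 to 1292086, was kept in ftz[Rpl] alone (0.89, against -0.31 to -0.05 in the other 6), although its probe at 1265599 was at 0.786 in B238. CG40191 (3 probes, chosen after its values were seen) separated the sets less clearly. It was kept in ftz[Rpl] and the 3 B strains (0.97 to 1.03), lost in G10 (0.17) and intermediate in bxd[68] and E(da) (0.49 and 0.46). The distal heterochromatin genes Nipped-A and Nipped-B, the latter a cohesin loader, were lost in all 7 strains (-0.49 to 0.05). With loess within arrays, both genes were intermediate in place of lost in bxd[68] and E(da), rl at 0.46 and 0.58 and l(2)41Ab at 0.44 and 0.48.

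Other listed 2R heterochromatin genes gave less clear values or a different order. RpL38, a ribosomal protein gene with 1 probe at 403538 of 2R, was chosen after its values were seen. Its index was 0.15 in ftz[Rpl], 0.32 in B[SV5] and 0.56 in G10, the 3 arrays of scan period 2, and 0.90, 0.86, 0.78 and 0.70 in B63, B238, bxd[68] and E(da), while loess gave 0.51 in bxd[68] and 0.33 in E(da). Maf1, a repressor of RNA polymerase III whose probes lie on unplaced sequence, had an index of 0.67 in ftz[Rpl] and -0.65 to -0.42 in the others, but the ftz[Rpl] value was 0.52 with normexp, 0.19 with loess and 0.29 in the deposited table. The probes of uex disagreed: 1 was lost in all 7 strains and 2 were kept in all 7, which gave gene indexes of 0.69 to 1.0, and 0.06 to 0.77 with loess. p120ctn, which encodes a catenin of cell junctions, ranged from -0.10 to 0.59, and Stlk, the first gene with at least 3 probes on the adjoining 2R sequence, from 0.01 to 0.56.

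The breakpoint fit chosen in advance did not place the breaks closely. It put the last kept probe at 203625 of the 2R arm in 6 strains and at 494796 in B238. On a scale where 2R follows 2RHet, its bootstrap intervals began at 0 in bxd[68], G10 and E(da), at 573091 in B[SV5], at 588599 in B63 and at 2909737 in ftz[Rpl] and B238, and ended between 3817033 and 3863427. With normexp, loess or the deposited table it gave 573091 in B[SV5] but 3105898 to 3738678 in B63 and B238, 3017746 to 3105898 in ftz[Rpl] and 0 to 51854 in the other 3. Of the 121 2RHet probes, 53 had an index above the midpoint in all 7 strains. Without those 53 probes, a choice made after seeing the data that itself rests on the index, the breaks fell in 3 places. In ftz[Rpl] sequence was kept up to 2574646 and lost from 3105718 of 2RHet (bootstrap interval 2391347 to 3807561 on the joined scale). uex, the nearest gene with at least 3 probes after that break, goes against it, at 0.97 in ftz[Rpl], since 2 of its 3 probes were kept in all 7 strains and left out of this fit. In B[SV5], B63 and B238 the fit put the change between the probes at 588599 and 609292 (496049 to 588599 in B[SV5] and B63, and up to 667003 in B238). The probe at 588599 was itself intermediate in these strains, at 0.569, 0.62 and 0.628. The change lay between l(2)41Ab, kept at 0.96 to 0.99, and MFS17, at -0.20 to -0.05. Among the breakpoint fits, this fit alone gave a break at this place in all 3. In bxd[68], G10 and E(da) it placed the break before the first remaining probe at 42322, with upper interval ends of 0, 61111 and 55539. That outcome was close to fixed, since the removal took 53 of the 59 2RHet probes above 0.5 in each of these strains.

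**Figure D2:**
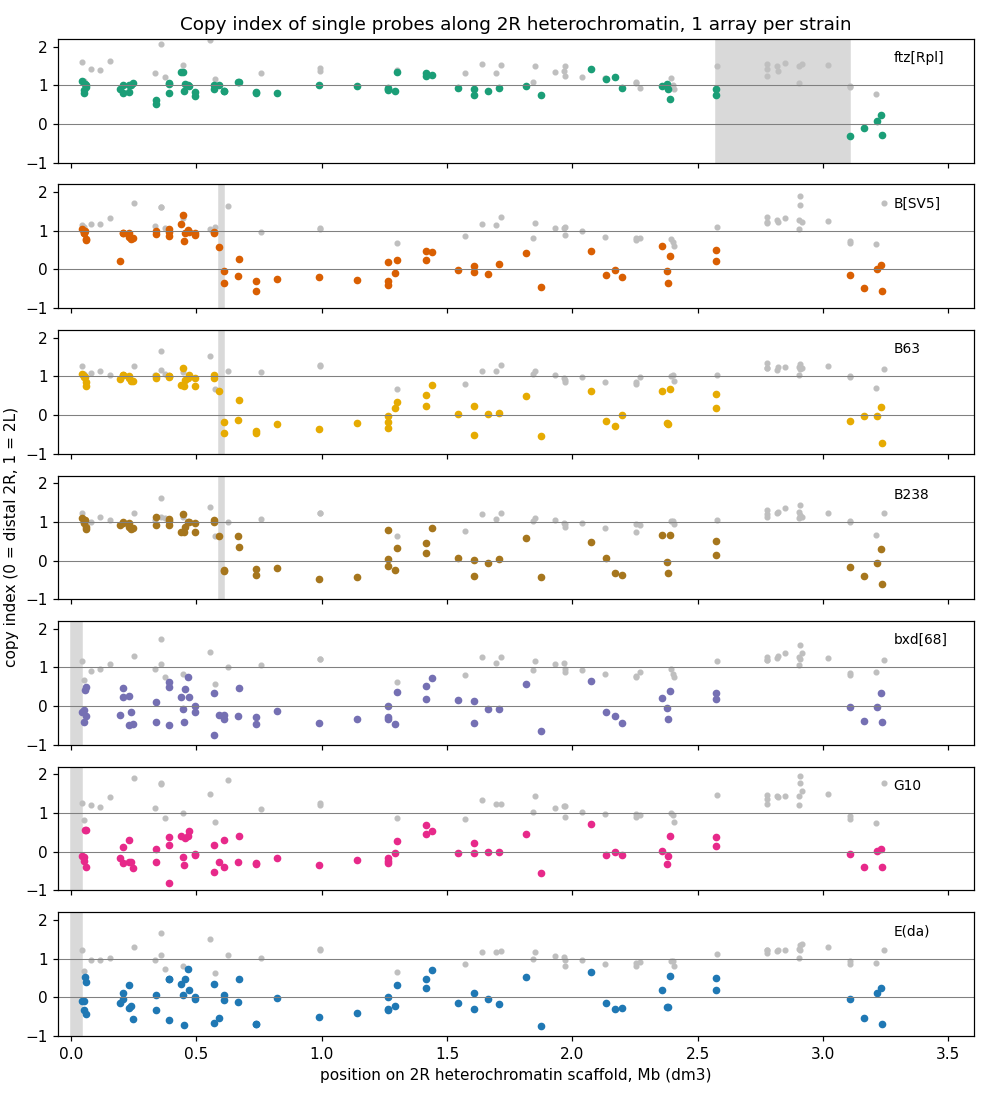
Copy index of single probes (vertical axis; 0 is distal 2R, 1 is 2L) against position on the 2R heterochromatin scaffold in Mb (horizontal axis), 1 panel per strain. Grey points are the 53 probes above the midpoint in all 7 strains, coloured points are the other probes, and the grey band runs from the last kept to the first lost probe fitted without the grey points, at 2574646 to 3105718 in ftz[Rpl] and 588599 to 609292 in the 3 B strains.

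Counts of single probes gave the same 3 sets. Of 121 2RHet probes, 113 were kept and 5 lost in ftz[Rpl]. In B[SV5], B63 and B238, 78, 82 and 82 were kept and 33, 30 and 29 lost, and in bxd[68], G10 and E(da), 53, 55 and 53 were kept and 51, 53 and 53 lost. The calls were nested: 52 probes were kept in at least 1 strain and lost in at least 1, and all 52 fit an order with ftz[Rpl] keeping most, then the 3 B strains, then bxd[68], G10 and E(da), against a median of 12 and a highest of 18 in 1000 relabellings. 6 orders tied, which left the order of bxd[68], G10 and E(da) unresolved, and the order of B238, B63 and B[SV5] rested on 1 probe per step. With a single threshold at 0.5, 55 of 63 probes fit. The call error was uneven, with 0.15% to 0.55% of 2L probes called lost but 9.8% to 15.3% of distal 2R probes called kept, and under loess the lost count in ftz[Rpl] was 10 and the kept count in G10 36, while the deposited table gave 9 lost in ftz[Rpl] and 52 in B[SV5].

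Unplaced sequence held many probes with the patterns of the 2R heterochromatin scaffold. Among 55504 probes of unplaced contigs, U and Uextra, 4125 (7.43%) were kept in at least 1 strain and lost in at least 1. That share was 42.98% on 2RHet, 5.90% on distal 2R, 0.88% on 2L and 0.14% on 3L. The share of varying probes was thus not far above that of distal 2R, so call error can account for many of them. The most frequent pattern, 762 probes of 500 distinct sequences, was kept in ftz[Rpl] only, and the next, 305 probes of 185 sequences, was kept in ftz[Rpl], B[SV5], B63 and B238. These are also the most frequent varying patterns on 2RHet itself, with 22 and 15 probes. The first pattern held 1.37% of the unplaced probes and the second 0.55%. On distal 2R, 14 of 2168 probes (0.65%) had the first pattern and 0 the second, and on 3998 2L and 4353 3L probes there were 0 of either. A further 46 probes of 31 sequences were lost in G10 and E(da) only, a pattern with 0 probes on 2RHet, distal 2R, 2L and 3L. These 46 were brighter in the reference channel, at a log2 signal of 10.17 against 7.33 for each of the first 2 patterns, and their median indexes in the B strains were 1.48 to 1.57, above the 2L level.

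The unplaced calls repeated where a sequence was on the array more than once. Of 534 pairs of probes with 1 sequence, usually 1 probe per strand, both called on every array and varying, 486 (91%) had the same pattern, as did 262 of 280 pairs for the first pattern, 120 of 125 for the second and 15 of 18 for the last. Median indexes were 0.95 in ftz[Rpl] and -0.18 to -0.06 elsewhere for the first, and 0.93 to 0.99 in the 4 keeping strains and -0.16 to -0.15 in the others for the second. Of all 4125 varying probes 1869 fit 1 nested order, against at most 674 in 1000 relabellings, and 167 were lost in ftz[Rpl] only, a pattern outside that order. With loess 6365 probes varied, and the first and last patterns held 445 and 24. Some named genes with unplaced probes were chosen after their values were seen. Of these, BckdhB (2 probes), CG41520 (3) and RYa (1) were kept in ftz[Rpl] only (1.01, 1.03 and 0.89). DIP-lambda (1) was kept in ftz[Rpl] and the 3 B strains (1.0 to 1.07). Release 6 lists all of them on 2R, but other unplaced genes that it lists there did not have these patterns. LSm1 (1 probe) was lost in every strain (-0.34 to -0.1), and snoRNA:U3:54Aa (1) was kept in every strain (0.82 to 1.21). Maf1 (4 probes), at 0.67 in ftz[Rpl], fell just short of a kept call there and was lost elsewhere.

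In a search for at most 1 step in copy number on each of 3L and 3R, each second-third strain had 1 called step. On these arms no step was called in a Y-autosome strain. In E(da), 3L from its tip to between 8409007 and 8420551 was higher than the rest, with a right minus left step of -0.54 (95% bootstrap interval -0.55 to -0.52), between ImpE1 (log2 0.61) and Cbl (0.22), which encodes a ubiquitin ligase. In bxd[68], 3R was higher from between 12591144 and 12615670 to its end, by 0.57 (0.54 to 0.61), between CG42342 (0.08) and the homeotic gene Abd-B (0.38). In ftz[Rpl], 3R was higher from between 2650405 and 2690825, by 0.45 (0.39 to 0.54), next to the homeotic gene Antp (0.27) on the higher side, while gpp, the nearest gene with at least 3 probes on the lower side, was at 0.62 against a window level of -0.11. 3 copies against 2 give 0.585. A short raised stretch of 3R in E(da), seen after the search and not tested, had windows from 13000001 and 13100001 at 0.456 and 0.702, against 0.048 and 0.077 in the windows on either side. The same 3 steps and no others were called in each of the 5 alternatives that could move them, with a smallest size of 0.494 in bxd[68], -0.478 in E(da) and 0.389 in ftz[Rpl].

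**Figure D3:**
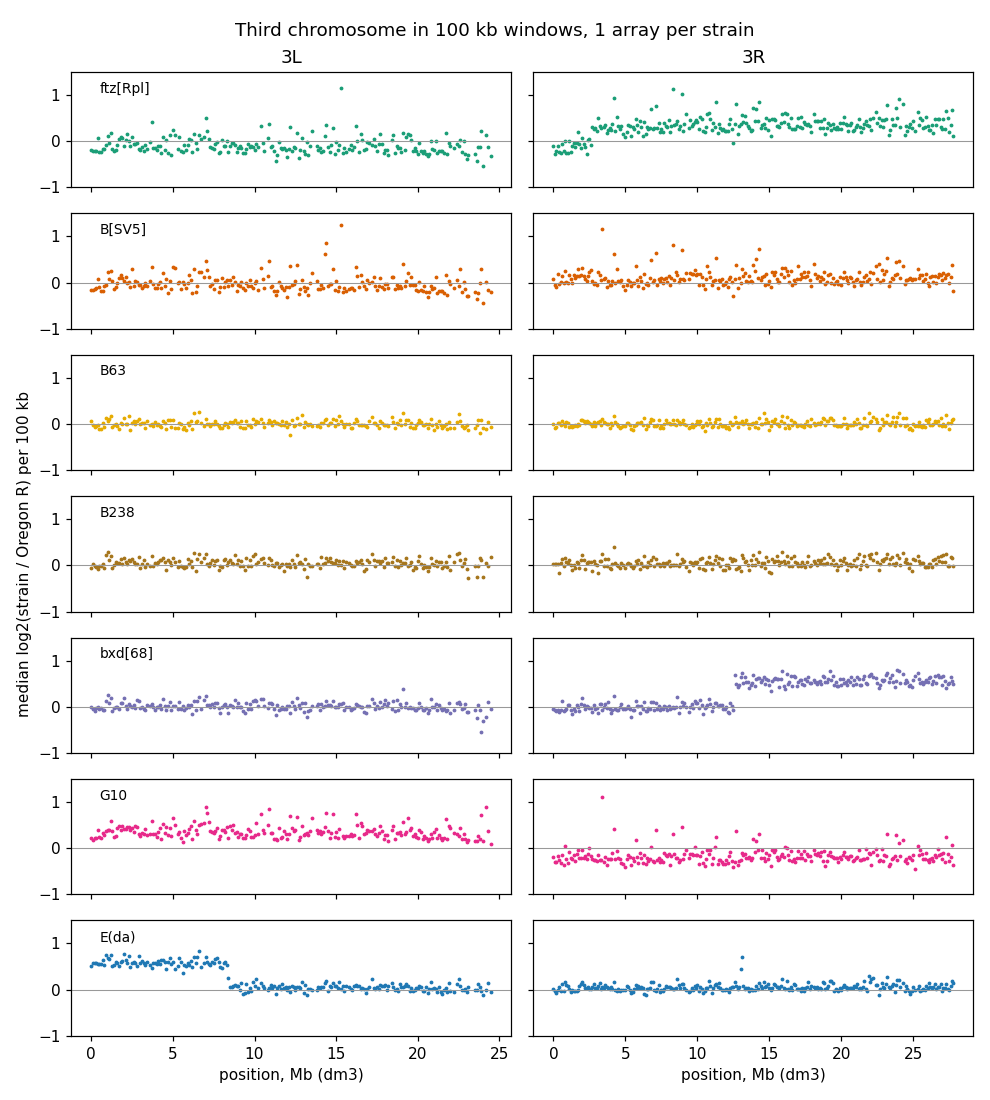
Median log2 ratio of strain over Oregon R in 100 kb windows (vertical axis) along 3L (left) and 3R (right) in Mb (horizontal axis), 1 panel per strain. The 3 second-third strains step at position 8400000 of 3L in E(da), 2700000 of 3R in ftz[Rpl] and 12600000 of 3R in bxd[68], and 3L lies above 3R as a whole in G10 (0.34 against -0.20).

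Other listed genes mostly lay near their arms. No listed 3L or multicopy gene had at least 3 probes. On 2L, RpL5, a ribosomal protein gene, wg, a Wnt ligand gene, and Adh, which encodes alcohol dehydrogenase, had indexes of 0.94 to 1.0, 0.73 to 0.96 and 0.96 to 1.35. Adh was higher on the 3 arrays of scan period 2 (log2 -0.41, -0.43 and -0.36 in ftz[Rpl], B[SV5] and G10) than on those of period 1 (-1.02 to -0.79). lt and step, in or near 2L heterochromatin, were highest in G10, at log2 -0.25 and 0.22 against -1.18 to -0.78 and -0.70 to -0.27 in the other 6, and step lay above the 2L level in all 7 strains (index 1.10 to 1.42). Sxl, the sex determination gene on the X, lay between -0.44 and 0.23, and pan and Ephrin on chromosome 4 between -0.42 and 0.12. X minus 2L was 1.22 ± 0.14 (SD, n = 4) in the Y-autosome and 0.91 ± 0.06 (SD, n = 3) in the second-third strains, with exact permutation p = 0.0571 and an adjusted p of 0.571. The class difference of 0.31 was 0.35 within scan period 1 and 0.26 within period 2, but class and slide coincide in period 1 and ftz[Rpl] alone stands for its class in period 2.

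Of the 10 genes with the widest range of index, only rl lies in 2R heterochromatin. The other 9 were htk, sta, dnc (a cAMP phosphodiesterase gene) and PsGEF on the X, axo on 3L, and tinc, Jupiter, Mhcl and red on 3R. By index all 9 were higher on each array of scan period 2 than on any of period 1, which held for 5 of the 9 when log2 values were set against 3L, for 8 with loess and for 7 in the deposited table. All 9 had their highest index in ftz[Rpl], where the 2L and distal 2R levels lie closest together, and htk, the widest, had log2 values of 1.67, 1.98 and 1.43 on the 3 arrays of period 2 and 0.00 to 0.39 on the 4 of period 1. Across all probes, limma called 12646 (16.2%) different between the periods, 10704 higher in period 2. On 3L, arrays correlated across probes at r = 0.93 to 0.95 within period 2, 0.56 to 0.80 within period 1 and 0.26 to 0.48 between them.

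The Y chromosome was lowest in B[SV5], though near 3L under loess, high in B63 and split in B238. Y minus 3L was -1.46 in B[SV5], -0.40 in G10, 0.39 in B238 and 1.01 in B63, and 0.28, 0.10 and 0.22 in ftz[Rpl], bxd[68] and E(da). The Y level was the median of 17 probes. In B238 their log2 values ran from -4.00 to 1.09, so the median there describes neither end. In B[SV5] all 4 listed Y genes with at least 3 probes were low: kl-3 and kl-5, dynein heavy chain genes of the sperm tail, at -1.86 and -1.70, CCY at -2.11 and WDY at -1.40. In B63 they were at 1.06, 0.88, 2.02 and 0.93, where 1 Y in every embryo against an even mix of sexes gives 1.0. B238 was split, with kl-3 and kl-5 at -2.68 and -2.12 but CCY and WDY at 1.34 and 0.84. Genes with fewer probes, chosen after their values were seen, followed this split in B238, with kl-2 at -3.01 and PRY at -3.78 but ARY, ORY, Ppr-Y and Pp1-Y2 at 0.93, 1.01, 1.01 and 1.09. The split in B238 held under loess (kl-3 at -1.23 and kl-5 at -0.68 relative to 3L, WDY at 1.34), but the low level of B[SV5] did so only in part. Its Y minus 3L was then -0.02, the lowest of the 7 strains next to 0.03 in B238, with kl-3 and kl-5 0.63 and 0.66 above 3L but WDY, PRY and Ppr-Y at -0.43, -1.03 and -2.22 (the last pair with 1 probe each). Loess also moved Y minus 3L to 0.996 in G10, 0.87 in ftz[Rpl], 0.82 in bxd[68] and 0.61 in E(da).

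**Figure D4:**
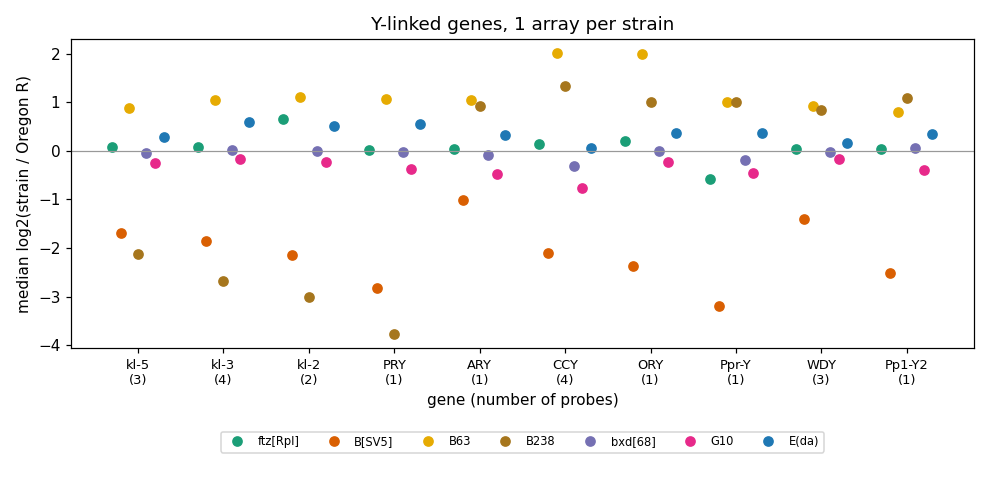
Median log2 ratio of strain over Oregon R (vertical axis) of 10 Y-linked genes (horizontal axis, number of probes in parentheses), 1 point per strain. B[SV5] lies below 0 at all 10 genes, although under loess WDY, PRY and Ppr-Y were the ones that stayed clearly below 3L, B63 at or above 0.80, and B238 below -2 at kl-5, kl-3, kl-2 and PRY but above 0.8 at the other 6.

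Between the translocation classes, few single probes differed and none had a gene name. limma called 23 of 78099 probes, 7 higher and 16 lower in the Y-autosome strains, and all 23 came from unplaced sequence. No named gene could therefore be listed. An unadjusted p under 0.05 was reached by 3144 probes (4.0%), fewer than the 3905 that chance gives. On 2R, whose probes share the level of the arm, 779 of 4336 did, with a median class difference of -0.74, but 0 passed adjustment. Other fits put the unadjusted number above 3905: 7272 with scan period as a block, 8392 with slide as a random block, 6203 without E(da) and 4479 without G10. Without 1 of the other strains it was 1766 to 3537. The count passing adjustment was unstable: it was 0 with loess or the deposited table, 4 with normexp (3 higher and 1 lower) and 10 when centred on 3L. Leaving out ftz[Rpl], B[SV5], B63, B238 or bxd[68] gave 35, 5, 4, 11 and 11. With slide as a random block it was 28 (10 higher and 18 lower). With slide as a fixed block it was 0, but only slide 3 holds both classes, so that fit compares ftz[Rpl] with B[SV5] alone and cannot show a difference between classes. With scan period as a block it was 26, and within period 1, where class and slide coincide, 0. Within period 2 it was 6047, but that sets ftz[Rpl] alone against B[SV5] and G10, with 1 residual degree of freedom, and has the same limit.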

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

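The tests of embryos carrying 2R, of a compressed array and of the scan period were chosen after their results were seen, and the others in this part before. Among 12 sets of values tested for a strain that stands apart from the rest, 5 held one, where chance gives about 1 in 20.

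Remaining 2R signal was highest in ftz[Rpl], whose 2R minus 2L of -1.72 stood apart from the other 6 strains (-4.03 to -3.12), although under loess G10 kept as much 2R signal (39.0% of 2L against 38.9%). Embryos with the usual dose of both 2L and 2R in the collection would also raise 2L. The signal would need 12% of such embryos, which predicts a 2L minus 3L of -0.78. The observed -0.90 lay -0.12 from that value, beyond 2 SD (SD 0.047) of the 5 other strains without G10. Embryos with 2R but without 2L would not raise 2L, so this test cannot count against them. A factor that compresses all ratios of the array predicts -0.45, and the observed value lay a further -0.45 below that. Leftover Cy5 background remains open as a candidate explanation, since dim 2R probes were raised relative to bright ones by 1.32 more than in the mean of the other 6 strains (-0.09 against -1.42). That test separates background from admixture only weakly, because 12% of embryos with 2R would also bring the difference to -0.47 (-0.76 to -0.19), and a mixture of both was not tested.

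G10 stood apart in 2L minus 3L (-1.45, among all 7 strains and among the Y-autosome strains), in X minus 3L among the Y-autosome strains (-0.42) and in 4 minus 3L (-0.70), which share 3L as a term. 3L was above 3R in G10 along the whole arm, at 3R minus 3L of -0.54. A GC trend, a brightness trend and the scan period were each argued against: the value was -0.53 with GC terms (bootstrap interval -0.55 to -0.52), at most -0.51 in any of the 4 brightness classes, and the other arrays of that scan period had 3R minus 3L of 0.12 or more. A candidate explanation is an extra dose of 3L in these embryos, where 3 copies against 2 give 0.585, and both 3LHet and 3RHet also lay above 3R in G10, by 0.38 and 0.35. G10 was the only array on its slide, so strain and slide cannot be told apart. The extra dose is a hypothesis found on these data, and a second DNA sample of G10 was not analysed here.

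Probes for the mitochondrial genome, which enter none of the tested differences between arms, lay below 3L on all 7 arrays, with a mean difference of -0.89.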

How the results depend on the processing

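The breakpoint without probes above the midpoint in all strains and the class contrast within or blocked by scan period were chosen after seeing the data. Of 281 values under alternatives, 17 were differences within an array centred on 3L, which cannot move, and 215 of the other 264 were rated as unchanged. For arm differences that meant the same direction and side of the threshold, or a shift below their spread. For breakpoints and steps it meant a value within the bootstrap interval, which for the breakpoints was wide. For counts of probes it meant a ratio within a fixed bound. Of the values rated as changed, 21 were arm differences without 1 strain, where the adjusted p of the sign-flip test rose to 0.0625. Signs changed for Y minus 3L in G10 under loess (-0.401 to 0.996) and, without single strains, for the mean 3R minus 3L (0.028 to at lowest -0.039) and Y minus 3L (0.02 to at lowest -0.146), which did not pass the test. No paired analysis was possible because each strain was on 1 array and the classes share no replicate pairs. Probes matching 1 place in the genome were not run, since no genome was used here, and 25 kb windows with 10 probes and scaffolds with 10 probes gave no value because none had so many. Signal over background limits the lost level, as up to 15.5% of 2R probes were not well above it in the strain channel.

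2R minus 2L shrank from -3.304 to -2.197 with normexp, -1.991 with loess and -1.568 in the deposited table, with the same direction and side of the threshold. Leaving out each strain moved 2R minus 2L between -3.568 and -3.183, 2L minus 3L between -1.022 and -0.927 and 4 minus 3L between -0.219 and -0.106 (without G10). Each then had an exact adjusted p = 0.0625 by the sign-flip test. With only these differences at the smallest p of 6 arrays, their adjusted p could not be lower, so those p-values say nothing of stability. With each strain left out, probes passing in the class contrast ran from 4 to 35.

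With loess within arrays, Y minus 3L was 0.642 over all strains, -0.02 in B[SV5], the lost count in ftz[Rpl] was 10, the kept count in G10 36, the unplaced probes that varied 6365, those kept in ftz[Rpl] only 445 and those lost in G10 and E(da) only 24, the bxd[68] step on 3R 0.528, and 0 probes passed in the class contrast. In the deposited table the lost counts were 9 in ftz[Rpl] and 52 in B[SV5], the steps 0.494 in bxd[68] and -0.478 in E(da), and 0 probes passed. With normexp the bxd[68] step was 0.542 and 4 probes passed, and centred on 3L 10 passed. With slide as a random block 28 passed, and as a fixed block, which compares ftz[Rpl] with B[SV5] alone, 0. Within scan period 1 0 passed, and within period 2 6047, from ftz[Rpl] alone against B[SV5] and G10. Without the probes above the midpoint in all strains the last kept probe moved from 3447507 to 2574646 in ftz[Rpl], to 588599 in B[SV5] and B63 and to 0 in bxd[68], G10 and E(da), and from 3738678 to 588599 in B238. For these shifts the cause was not tested.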

Other observations

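The test of a third-chromosome place for a 2RHet segment and the count of other splits were chosen after their results were seen, and the other tests in this part before. Genes named here were chosen after their values were seen.

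Strains also differed in regions near arm ends and centromeres. In G10, 2L was higher from position 22600001 on, by 0.63 (log2), the only step called on 2L. ftz[Rpl] had an uncalled step of 0.54 at the same place, and bxd[68], B63 and E(da) had uncalled steps of 0.18 to 0.26 there or next to it. G10 alone had low values for the unplaced genes Gpa2 and klhl10 (1 probe each, indexes 0.36 and -0.40, against 0.94 to 1.12 in the other 6). On the X, the first 300000 bases were higher than the rest in B63, the only step called there, with a right minus left difference of -0.62, and the largest uncalled step on that arm, in B238, was at the same place at -0.62; the median over probes of that stretch lay 0.58 and 0.51 above the X in B63 and B238 and -0.25 to 0.05 from it in the other 5. B63 and B238 were the only arrays on their slide and scan day, so strain and slide cannot be told apart for this stretch. The Y-linked Su(Ste) probes on unplaced sequence were low in B[SV5] (Su(Ste):CR42411 at -2.45, but Su(Ste):CR40820 at 0.19) and high in ftz[Rpl] (1.13 to 1.57) and B63 (1.30 to 1.89).

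Probes made of simple satellite repeats varied widely between strains. The 439 probes with the dodeca repeat CGGTCCCGTACT, which lies in third-chromosome heterochromatin, had medians of 2.78 in G10, 1.69 in ftz[Rpl], 1.52 in B[SV5], 1.04 in B63, 1.0 in E(da), 0.18 in bxd[68] and 0.07 in B238. The 3 highest were the 3 arrays of scan period 2, and the difference between periods correlated with GC content at r = 0.56 across 3L probes, which are not independent replicates, so period and strain were not separated for these probes. Dodeca repeats at the dose of the third chromosome would lie near 3L on every array, and the largest distance from 3L was 2.44. The 76 probes with AATAACATAG lay below dodeca on 5 of 7 arrays (mean -0.83 ± 1.04, SD, n = 7, exact two-sided sign-flip p = 0.0938). The dodeca signal did not stay near 3L, so this comparison says nothing about loss of a second-chromosome part. Their own medians lay between 0.18 and 0.64, above 0 in all 7 strains, a narrower range than that of dodeca.

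A segment of the 2RHet scaffold was not lost in any strain. Its 12 probes from 2774967 to 3017746 had medians of -0.14 to 0.29, with 0.29 in G10, where 3L was 0.34. The segment lay closer to 3L than to 2L on 7 of 7 arrays, and 9 of its probes carry genes that Release 6 lists on 3L (l(3)80Fj, eIF4B and CR14578), so a place on the third chromosome is a candidate explanation for why it stayed. Repeats elsewhere in the genome that bind the probes could not be ruled out, since the reference signal was 0.99 (log2) above that of 22 2RHet probes lost in 6 strains, between the bounds set in advance.

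For the 23 probes passing between the translocation classes, chance cannot be excluded: 6 of the 35 splits of the 7 arrays, the real one included, gave as many. The highest of the others, with 12646 probes, is the split by scan period, a count far above the real one, which points to a structure of the arrays by period. With scan period as a block the class contrast gave 26 probes, and within period 1, where class and slide coincide, it gave 0. Within period 2 it gave 6047, from ftz[Rpl] alone against B[SV5] and G10, which cannot show a class difference.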
